A study of Mus musculus with 4 samples.

How the data were processed

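RNA from 4 samples of mouse brown adipocytes was measured on Affymetrix mouse PM strip arrays, with 2 arrays of cells expressing a scrambled shRNA and 2 of cells expressing an shRNA against Blnc1. Per the labels' protocols, total RNA was taken with Trizol after 6 days of differentiation, and biotin-labelled antisense RNA was made from 250 ng with a 3' in vitro transcription kit. That method starts copying at the poly(A) tail, so probe sets far from the 3' end read lower where RNA is broken. The values are the log2 expression values deposited by the authors, with 1 value per probe set and array. The tools affy, RMA and limma are named, per the submitters' processing notes, with no versions, roles or order. The log2 scale was taken from the values, which run from 1.05 to 12.36. The exact normalization is not given in the sources used here. Scanner files and detection calls were not used here.

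The value table holds 45141 probe sets, of which 104 are controls. Of the other 45037, the platform annotation pairs 28898 with exactly 1 gene symbol, 551 with several and 15588 with none. Of the 28898, 28689 had an Entrez ID in a RefSeq gene table (assembly GRCm38.p6), which was used for names only, and 0 symbols needed an update. No genome build is named for the arrays, so no coordinates are given. A gene was represented by its probe set with the highest mean over the 4 arrays among those with exactly 1 symbol. This gave 17097 genes, 7180 of them with more than 1 probe set. Ppargc1a, Otop1, Hnrnpu and Blnc1 are not named by the annotation used here.

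The background log2 value, 2.55, is the highest value of any antigenomic control probe set with 3 to 24 G or C bases on any array. Probe sets above it made up 62.8% and 63.0% of the scramble arrays and 60.4% and 60.3% of the knockdown arrays, and a group mean at or below it is called at background. Both groups were at background for 4210 tested genes. Of the called genes, 2878 had both groups above background, 214 had 1 group at background and 77 had both at background.

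Tests were run in R 4.3.3 with limma 3.58.1: lmFit and eBayes on all 45037 probe sets, group as the only term, two-sided, with Benjamini-Hochberg adjustment over the genes and a threshold of 0.05. The residual degrees of freedom were 2 and the prior ones 4.93, and the median standard error of a log2 fold change was 0.11. Gene lists were tested with camera at a preset correlation of 0.01, adjusted over the 23 lists chosen beforehand. Of these, 13 passed 0.05 with the preset correlation and 0 with a correlation estimated per list, where 2 had an unadjusted p under 0.05. With an estimate, camera uses the 2 residual degrees of freedom, and with the preset far more, so few lists could pass with an estimate. The test fry, which does not compare a list with other genes, called 16. Their counts were also adjusted over the list alone, and medians carry 95% bootstrap intervals from 2000 draws over genes, which are not independent. The hepatocyte, FOXO target and PPAR target lists were added after the leading genes had been seen and were adjusted apart from the others. Plots were drawn with matplotlib 3.10.9.

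The test, the gene lists, the alternatives and the rule for named genes were chosen before the data were examined. The rule takes a set of fixed markers, the 10 largest called changes in each direction whose groups do not overlap, and up to 4 called members of each list with the largest change, of which examples are given in the text. No gene was skipped for a clone or locus name. Where a count is 5 or fewer, members outside the rule are named too, which were chosen after their values were seen. The alternatives were quantile normalization, centring each array on its median, leaving out the dimmest 40 percent of genes, eBayes with a trend or robust, the mean of all probe sets of a gene, every probe set on its own, the replicate number as a block, leaving out each array in turn, limma's treat against 0.5, camera with an estimated correlation, and fry. Where 1 array of a group remained, it was assumed to vary like those of the other group.

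The fit was tested on 5 simulated data sets of the knockdown against scramble comparison, with 17097 genes and 200 changed genes each. It recovered 5.07% of genes changed by 0.5 log2 units, 88.1% of those changed by 1 and 98.8% of those changed by 2, and 4.35% of its calls were false. A list of 30 genes shifted by 0.3 was called in 5 of 5 data sets, and 2.2% of unshifted lists were called. The simulated noise was independent between genes and held no difference in RNA quality between the groups. The 200 changed genes are also fewer than the 3169 called in the data, so these rates need not hold there.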

Results

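Gene expression was measured in mouse brown adipocytes that carried either a scrambled control short hairpin RNA (shRNA) or an shRNA against Blnc1 (brown fat lncRNA 1), a long noncoding RNA. The cells were harvested after 6 days of differentiation, and each array received labelled material made from 250 ng of total RNA. There were 2 scramble arrays and 2 Blnc1 knockdown arrays, described as biological replicates, and this small number limits the precision of every value. The comparison asks which transcripts depend on Blnc1 in differentiated brown adipocytes. No probe set carries the name Blnc1 in the annotation used here, so the level of the target itself was not analysed here. Across the probe sets, replicates correlated at r = 0.994 (scramble) and r = 0.996 (knockdown), and arrays of different groups at r = 0.982 to 0.984. These correlations are across probe sets, which are not independent replicates. The median log2 value per array was 2.98 on both scramble arrays, and 2.92 and 2.91 on the knockdown arrays.

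Several measures of RNA quality and composition moved with the groups. The log2 ratio of the 3' to the 5' control probe set of Actb was 1.07 ± 0.11 (SD, n = 2) in scramble and 1.82 ± 0.08 (SD, n = 2) in knockdown. That of Gapdh was 0.06 ± 0.04 and 0.37 ± 0.04. The probe set for the middle of 18S ribosomal RNA had a mean log2 value of 4.78 in scramble and 6.82 in knockdown. Liver transcripts were present in the scramble arrays: Alb, the serum albumin gene, read 6.28 and 5.70 there, against 4.43 and 2.50 in the knockdown arrays, where 2.55 is the background log2 value.

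Among the genes called, those on the brown thermogenic and oxidative phosphorylation lists were mostly lower on the Blnc1 knockdown arrays, and those on the extracellular matrix, lipogenesis, cholesterol synthesis, interferon response and cell cycle lists were mostly higher. Of the 23 gene lists, 13 passed an adjusted p of 0.05 by camera with a preset correlation. With an estimated one 0 passed, and 2 had an unadjusted p under 0.05. The estimated version rests on 2 residual degrees of freedom, so few lists could pass it. The thermogenic markers Ucp1 and Cidea were 3.64-fold and 4.02-fold lower. The general fat cell markers Adipoq and Fabp4 were not called, with log2 fold changes of 0.07 and 0.02 from probe sets near the top of the scale, and a dimmer probe set of Fabp4 had a log2 fold change of -0.69. Of 17097 genes tested with limma, 3169 (18.5%) passed an adjusted p of 0.05, with 1941 higher and 1228 lower in knockdown. A change of at least 1 log2 unit was seen for 430 of them, 367 higher and 63 lower. The balance of directions depended on the scaling: quantile normalization gave 1514 higher and 1564 lower genes, and centring each array on its median gave 2383 higher and 844 lower. With knockdown replicate 1 or replicate 2 left out, the number of called genes was 1232 and 1050.

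The largest rise was that of the histone H3 gene H3c15, 11.3-fold (adjusted p = 0.000328), whose value is uncertain because histone H3 genes have near-identical copies. Aspn, which encodes the small matrix proteoglycan asporin, was 9.12-fold higher, and the collagen genes Col8a1 and Col11a1 were 8.63-fold and 6.23-fold higher. The integrin-related genes Itgbl1 and Itga8 rose 7.52-fold and 5.80-fold. Ecrg4, Ahnak2, Enpep and Maged2 completed the 10 largest rises, at 7.03, 6.27, 6.04 and 5.23-fold. Adjusted p-values for these 10 genes lay between 0.000134 (Col8a1, Ahnak2, Col11a1) and 0.000427 (Ecrg4). With the mean of all probe sets of a gene, the log2 fold change was 1.44 in place of 3.11 for Col8a1, 1.35 in place of 2.54 for Itga8 and 1.92 in place of 2.81 for Ecrg4, where the means of Col8a1 and Itga8 include a probe set at background. The probe sets of Aspn and Ecrg4 are of a type that can detect more than 1 transcript.

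Among the lower genes, Depp1 fell 11.4-fold, from a mean log2 value of 9.79 to 6.28 (adjusted p = 0.000134). Depp1 is a target of FOXO transcription factors. Mb, which encodes the oxygen-binding protein myoglobin, fell 4.57-fold (adjusted p = 0.00114), and the chloride channel gene Ano1 fell 4.53-fold (adjusted p = 0.000238). Orly and Mmd2 were 4.44-fold and 3.96-fold lower, each from a probe set that, like that of Ano1, can detect more than 1 transcript. With the mean of all probe sets the log2 fold change was -1.22 in place of -2.19 for Mb, -0.99 in place of -2.15 for Orly and -1.29 in place of -1.99 for Mmd2, where the mean of Orly includes a probe set at background. The 10 largest falls also held 4 genes known for their expression in liver, Alb (5.74-fold), Serpina1c, Cyp2e1 (4.90-fold) and Itih4 (4.11-fold). Serpina1c read 4.90 in scramble, and its knockdown mean of 2.48 was at background. Alb had a standard error of 0.55 log2 units and an adjusted p of 0.0225, which was 0.0638 without scramble replicate 1. The knockdown arrays differed for Alb, with 4.43 on replicate 1 and 2.50, at background, on replicate 2, so the size of its fall is inexact. Without replicate 2 its log2 fold change was -1.56 in place of -2.52. Cidea completed the 10 largest falls.

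Of 35 measured brown thermogenic genes, 16 were lower, 3 were higher and 16 were not called, with a median log2 fold change of -0.31 (95% bootstrap interval -0.60 to -0.12). The list test, camera, gave an adjusted p of 2.93e-05, and adjusted p = 0.197 with an estimated correlation. Adjusted over the list alone, 21 members were called. Ucp1, the uncoupling protein that lets brown fat mitochondria produce heat (Entrez Gene 22227), went from 7.62 ± 0.15 to 5.75 ± 0.32 (log2, SD, n = 2; adjusted p = 0.00103). Cidea, a lipid droplet protein abundant in brown fat (Entrez Gene 12683), went from 8.34 ± 0.08 to 6.33 ± 0.06 (adjusted p = 0.000291). The nuclear receptor gene Ppara was 3.61-fold lower (adjusted p = 0.000328), and Pdk4, whose product inhibits pyruvate dehydrogenase, was 3.52-fold lower (adjusted p = 0.000333). Dio2, which encodes the enzyme that activates thyroid hormone, read 3.40 in scramble and 2.45 in knockdown, the latter at background (adjusted p = 0.00665). The higher members were Elovl3, a fatty acid elongase gene (2.10-fold, adjusted p = 0.00169), Lhx8 and Acot2. With the mean of all probe sets the log2 fold change of Ppara was -1.04 in place of -1.85. That of Dio2 was -0.53 in place of -0.95, where its other probe sets were at background. Lower members numbered 9 without knockdown replicate 1 and 11 without replicate 2, with 1 higher member, in place of 3, each time and without scramble replicate 2. The same knockdown arrays had the higher Actb 3'/5' log2 ratio (1.82 against 1.07), and the scramble arrays had the higher Alb values (mean 5.99 against 3.47).

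**Figure D1:**
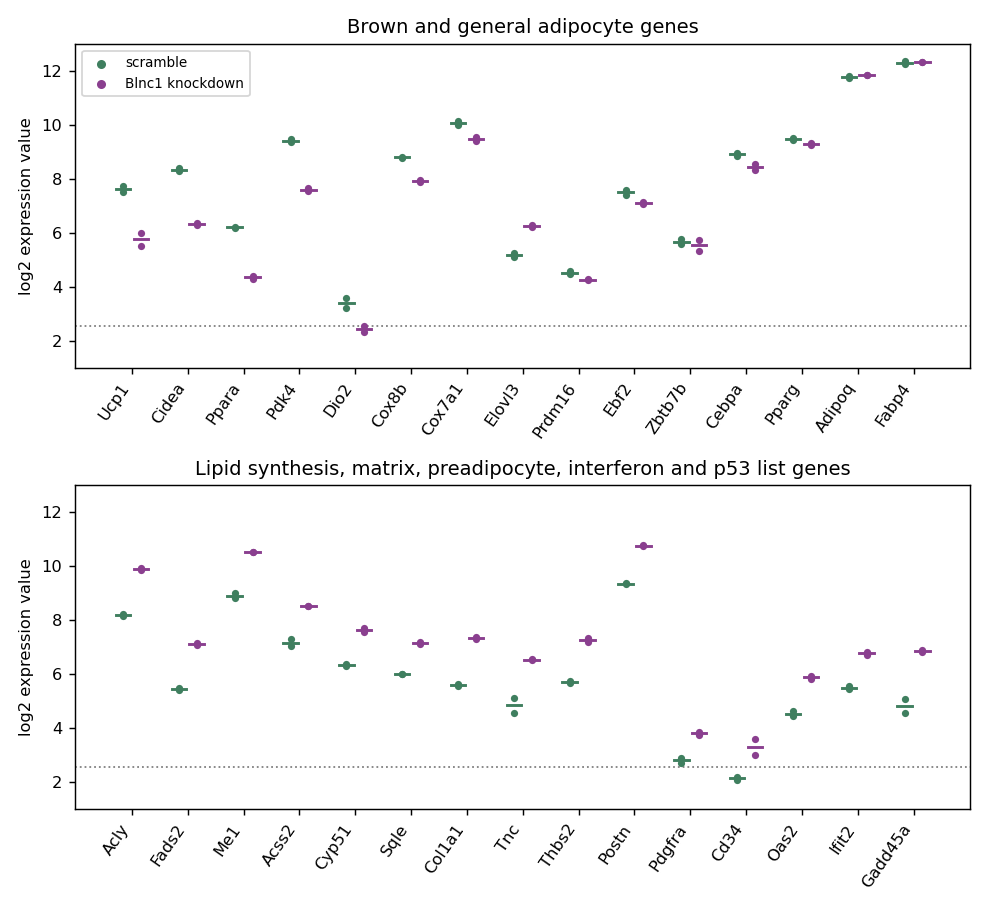
Log2 expression values per array (points) and group means (bars) of 15 brown and general adipocyte genes (upper panel) and of 15 lipid synthesis, matrix, preadipocyte, interferon and p53 list genes (lower panel), for scramble (green) and Blnc1 knockdown (purple), with the background log2 value of 2.55 as a dotted line. Ucp1 went from a mean of 7.62 to 5.75, Adipoq read 11.78 and 11.85, and the genes of the lower panel were higher on both knockdown arrays.

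Of the 13 measured marker genes chosen beforehand, 7 were called. Beside Ucp1, Cidea, Dio2 and Elovl3 these were the cytochrome oxidase subunit genes Cox8b and Cox7a1 and the adipogenic factor gene Cebpa. Cox8b was 1.84-fold lower (adjusted p = 0.00225) and Cox7a1 was 1.52-fold lower (adjusted p = 0.0126; 0.091 and 0.0518 without knockdown replicates 1 and 2). Cebpa was 1.38-fold lower with an adjusted p of 0.0368, which became 0.0964 without scramble replicate 1, and 0.0727 and 0.229 without knockdown replicates 1 and 2. Ebf2, a transcription factor gene of the brown fat lineage, had a log2 fold change of -0.40 and an adjusted p of 0.0523. That adjusted p was 0.0264 after quantile normalization and 0.00602 in eBayes with a trend. With the mean of all probe sets of Ebf2 it was 0.0819, with a log2 fold change of -0.26. A dimmer probe set of Ebf2, above background, had a log2 fold change of -0.06. Prdm16 (-0.26, adjusted p = 0.134), Pparg (-0.17, adjusted p = 0.28), Zbtb7b (-0.14, adjusted p = 0.551), Adipoq (0.07, adjusted p = 0.682) and Fabp4 (0.02, adjusted p = 0.91) were not called. In eBayes with a trend Pparg had an adjusted p of 0.037. A dimmer probe set of Fabp4 had a log2 fold change of -0.69, opposite in sign to the brightest, which read above 12 on every array and lies near the top of the scale. The brightest probe set of Fabp4 also changed sign after quantile normalization, to -0.04.

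Genes that fat cells of any type express went both ways. Of 31 general adipocyte genes, 5 were higher, 4 were lower and 22 were not called, and 11 were called when adjusted over the list alone. The median was -0.07 (-0.001 after median centring) and the mean 0.03, camera gave the direction down with an adjusted p of 0.983, and fry, a test of a shared direction, gave the direction up with 0.688. Lep, the leptin gene, was 3.17-fold higher (adjusted p = 0.00261), and the glycerol phosphate dehydrogenase gene Gpd1 was 1.81-fold higher (adjusted p = 0.00263), with a log2 fold change of 0.85, or 0.42 with the mean of its probe sets, 1 of them at background. Dgat2, Fabp5 and Cd36 were the other higher members, and Pnpla2, Cebpa, Lpin1 and Plin4 the lower ones. Without knockdown replicate 1 or replicate 2, the numbers were 2 higher and 0 lower, and without scramble replicate 1 they were 4 and 0. Among 18 white fat selective genes, 5 were higher (Lep, Psat1, Wfdc21, Igfbp3 and Nnmt), 1 was lower (Slc7a10), and 7 were called over the list alone. Psat1, an enzyme of serine synthesis, was 2.03-fold higher (adjusted p = 0.00171), and the list test gave an adjusted p of 0.136, or 0.0218 with the mean of all probe sets of a gene. Without knockdown replicate 1, 3 of the white fat selective genes were higher, and Wfdc21 had an adjusted p of 0.0509.

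Transcription regulators of brown fat were lower in 10 of 29 cases and higher in 1 (Plac8), with 13 called when adjusted over the list alone and a median of -0.16, which was -0.29 after quantile normalization and -0.09 after median centring. The camera adjusted p was 0.00525, and adjusted p = 0.197 with an estimated correlation. Beside Ppara, Irf4, an interferon regulatory factor that also acts in fat cells, was 2.27-fold lower (adjusted p = 0.00296), a log2 fold change of -1.18, or -0.63 with the mean of its probe sets, 1 of them at background. Ppargc1b, a coactivator of mitochondrial genes, was 1.79-fold lower (adjusted p = 0.00261). With knockdown replicate 1 or replicate 2 left out, 4 members were lower, without scramble replicate 1 there were 6, and after centring each array on its median 5.

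Of 70 measured oxidative phosphorylation genes, which encode the respiratory chain and ATP synthase, 13 were lower, 0 were higher and 57 were not called, with 14 called over the list alone. The list test gave an adjusted p of 9.03e-06, and adjusted p = 0.197 with an estimated correlation. The median was -0.19 (95% bootstrap interval -0.22 to -0.14), or -0.12 after median centring. The complex I gene Ndufs4 was 1.69-fold lower (adjusted p = 0.00366), a log2 fold change of -0.76, or -0.49 with the mean of its probe sets (1 of them at background), and the complex III gene Uqcrc1 was 1.53-fold lower (adjusted p = 0.00781; 0.0694 without knockdown replicate 2). The number of lower members was 2 without knockdown replicate 1, 1 without replicate 2, 7 and 6 without scramble replicates 1 and 2, 8 after quantile normalization and 7 after median centring.

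Of 22 mitochondrial biogenesis genes, 9 were lower and 0 higher, 10 were called over the list alone, and the median was -0.24 (camera adjusted p = 0.00124, and adjusted p = 0.197 with an estimated correlation). Polrmt, the mitochondrial RNA polymerase gene, was 1.63-fold lower (adjusted p = 0.00643; 0.0537 without knockdown replicate 1), and Ppargc1b belongs to this list too. Without knockdown replicates 1 and 2, 1 and 2 members were lower. After median centring 5 were lower, and 6 and 4 without scramble replicates 1 and 2. Of 22 fatty acid oxidation genes, 5 were lower (Echs1, Cpt1b, Ehhadh, Eci1 and Etfa) and 2 higher (Cpt1a and Acot2), 8 were called over the list alone, and the list test gave an adjusted p of 0.414. Echs1, an enoyl-CoA hydratase, was 2.16-fold lower (adjusted p = 0.00106). Cpt1a and Cpt1b, isoforms of the enzyme that commits fatty acids to oxidation, moved apart: Cpt1a was 2.05-fold higher and Cpt1b 1.64-fold lower (adjusted p = 0.0124 and 0.00755; 0.0645 and 0.0585 without knockdown replicate 1). Of 18 TCA cycle genes, 4 were lower (Ogdh, Dlat, Suclg2 and Suclg1) and 1 higher (Pdha1), 7 were called over the list alone, and the adjusted p of the list was 0.323. Lower TCA cycle members numbered 1 and 2 without scramble replicates 1 and 2, and no member was called without knockdown replicate 1 or replicate 2. Lower fatty acid oxidation members numbered 1 and 2 without knockdown replicates 1 and 2, and 3 without scramble replicate 2. Ogdh had an adjusted p of 0.114 with the mean of its probe sets. In these knockdown arrays the Gapdh 3'/5' log2 ratio was 0.37, against 0.06 in scramble.

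**Figure D2:**
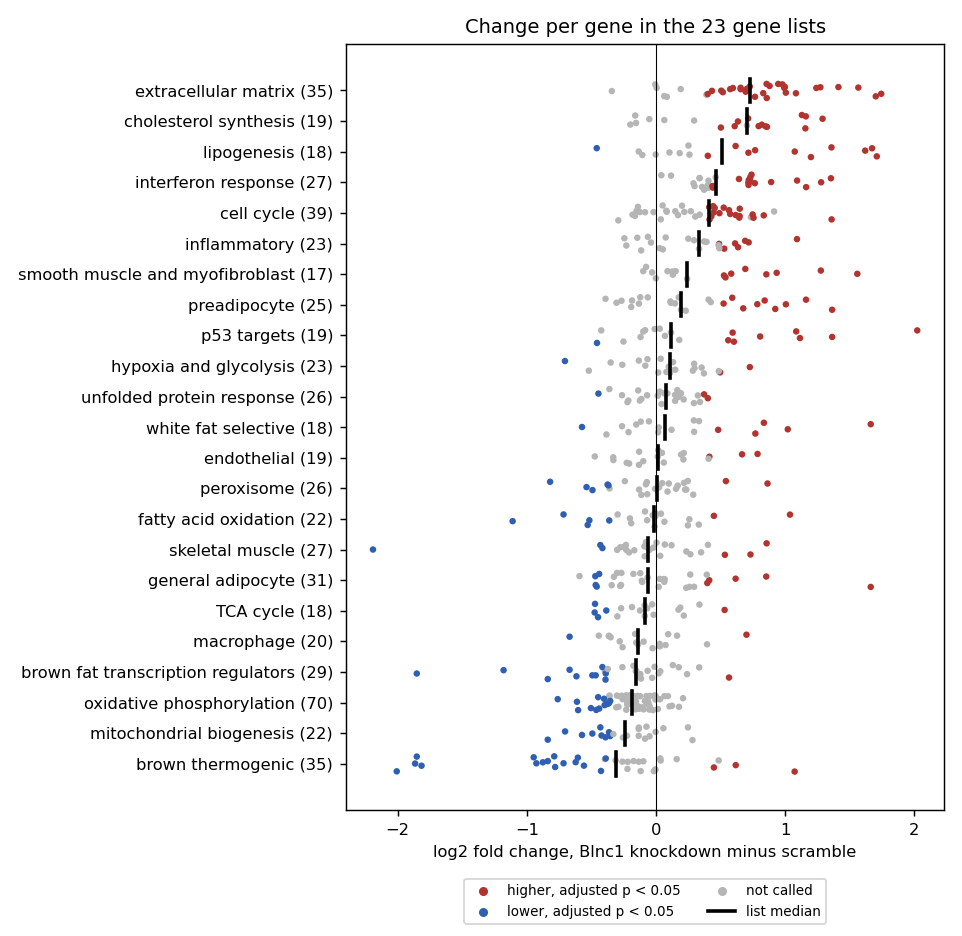
Log2 fold change (Blnc1 knockdown minus scramble) of each measured gene in the 23 gene lists, with the number of measured genes in brackets, coloured by whether the gene passed an adjusted p of 0.05, and the list median as a black bar. The medians run from 0.73 for the extracellular matrix list to -0.31 for the brown thermogenic list.

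Of 18 lipogenesis genes, 10 were higher, 1 was lower (Lpin1) and 7 were not called, with 11 called over the list alone and a median of 0.51 (95% bootstrap interval 0.18 to 1.07). The list test gave an adjusted p of 3.14e-06, and adjusted p = 0.339 with an estimated correlation. Acly, which makes cytosolic acetyl-CoA from citrate, was 3.27-fold higher (adjusted p = 0.000338). The desaturase gene Fads2 was 3.19-fold higher (adjusted p = 0.000338), Me1, a malic enzyme gene that supplies NADPH, 3.07-fold (adjusted p = 0.000427), and Acss2, which makes acetyl-CoA from acetate, 2.56-fold (adjusted p = 0.00097). Of 19 cholesterol synthesis genes, 12 were higher and 0 lower, with 14 called over the list alone and a median of 0.70. That list had an adjusted p of 1.64e-06, and adjusted p = 0.309 with an estimated correlation. Cyp51, Sc5d, Sqle and Idi1 were 2.44, 2.24, 2.23 and 2.19-fold higher, with adjusted p-values of 0.000851 to 0.000979. The arrays with these higher values also read higher at the middle probe set of 18S ribosomal RNA (6.82 against 4.78). Its 3' probe set had a log2 fold change of 0.40 (limma adjusted p = 0.284 over the control probe sets).

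Of 35 measured extracellular matrix genes, 28 were higher, 0 were lower and 7 were not called, 30 were called over the list alone, and the median was 0.73 (95% bootstrap interval 0.59 to 0.88). Col1a1, the main fibrillar collagen gene, was 3.35-fold higher (adjusted p = 0.000331). The matricellular genes Tnc, Thbs2 and Postn were 3.25, 2.96 and 2.66-fold higher (adjusted p = 0.00159, 0.000427 and 0.000446), although Tnc had a log2 fold change of 0.85 in place of 1.70 with the mean of its probe sets, 1 of them at background. The list test gave an adjusted p of 3.83e-16, and adjusted p = 0.197 with an estimated correlation. Of 25 preadipocyte genes, 9 were higher, 0 lower and 16 not called, with 12 called over the list alone and a median of 0.19. The list had a camera adjusted p of 0.00493, and adjusted p = 0.197 with an estimated correlation. The adhesion receptor gene Cd44 was 2.57-fold higher (adjusted p = 0.00252), a log2 fold change of 1.36, or 0.53 with the mean of its probe sets (2 of them at background), and the growth factor receptor genes Pdgfra and Pdgfrb were 2.01-fold and 1.90-fold higher (adjusted p = 0.00225 and 0.00316). Pdgfra was dim, at 2.81 in scramble, and Cd34, with a scramble mean of 2.14, was at background there. Smooth muscle and myofibroblast genes were higher in 8 of 17 cases and lower in 0, with 8 called over the list alone, a median of 0.24 (0.42 without scramble replicate 1), a camera adjusted p of 0.000192, and adjusted p = 0.197 with an estimated correlation. Ccn2 and Ccn1, secreted matrix-associated proteins, were 2.94-fold and 2.42-fold higher (adjusted p = 0.0013 and 0.00104), and 5 and 4 members were higher without knockdown replicates 1 and 2. The Actb 3'/5' log2 ratio, 1.82 against 1.07, was higher on the same arrays.

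Interferon response genes were higher in 15 of 27 cases and lower in 0, with 23 called over the list alone and a median of 0.46 (95% bootstrap interval 0.40 to 0.73). Oas2, a sensor of double-stranded RNA, was 2.56-fold higher (adjusted p = 0.000918), and Ifit2 and Ifit3 were 2.42-fold and 2.24-fold higher (adjusted p = 0.000858 and 0.00253). The list test gave an adjusted p of 1.84e-11, and adjusted p = 0.197 with an estimated correlation. Without knockdown replicate 2, 8 members were higher. Of 23 inflammatory genes, 7 were higher, 0 lower and 10 called over the list alone, with a median of 0.33, or 0.20 without knockdown replicate 1 (camera adjusted p = 0.00144, and adjusted p = 0.197 with an estimated correlation). The serum amyloid gene Saa3 was 2.13-fold higher (adjusted p = 0.00252) and the chemokine gene Cxcl12 1.64-fold (adjusted p = 0.00438, or 0.17 with the mean of its probe sets). The number of higher inflammatory genes was 3 and 2 without knockdown replicates 1 and 2. On the knockdown arrays the Actb 3'/5' log2 ratio (1.82 against 1.07) and the B1 repeat signal (9.66 against 8.35) were higher as well.

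Cell cycle genes were higher in 18 of 39 cases and lower in 0, with 20 called over the list alone, a median of 0.41 and a camera adjusted p of 3.14e-06 (adjusted p = 0.339 with an estimated correlation). The mitotic kinase gene Aurkb was 2.57-fold higher from a probe set that can detect more than 1 transcript (adjusted p = 0.000611), while its other probe set, of like brightness, had a log2 fold change of 0.20, and the mean of both was 0.78. The mitotic kinesin gene Kif20a was 1.78-fold higher (adjusted p = 0.0047). With knockdown replicate 1 or replicate 2 left out, 5 members were called. Of 19 p53 target genes, 8 were higher and 1 lower (Trp53inp1), with 9 called over the list alone, a median of 0.12 (0.05 after quantile normalization and 0.20 without knockdown replicate 1), a camera adjusted p of 0.00826, and adjusted p = 0.339 with an estimated correlation. With dim probe sets left out the adjusted p of this list was 0.0921. Gadd45a, a stress-induced growth arrest gene, was 4.06-fold higher (adjusted p = 0.00092), and Zmat3 and Eda2r were 2.16-fold and 2.12-fold higher (adjusted p = 0.00288 and 0.00127). Pmaip1 went from 1.97, at background, to 3.33. Higher p53 targets numbered 5 and 4 without knockdown replicates 1 and 2. The middle 18S probe set again read higher on these arrays (6.82 against 4.78).

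The skeletal muscle, macrophage, endothelial, unfolded protein response, hypoxia and glycolysis, and peroxisome lists were not called with camera. Only 10 of 20 macrophage, 12 of 19 endothelial and 18 of 27 skeletal muscle genes were above background in a group, which limits what these lists can show. Of 27 skeletal muscle genes, 3 were lower (Mb, Myod1 and Pax7), 3 higher (Tnnc2, Myl1 and Actn3) and 6 called over the list alone (adjusted p = 0.617). The direction of this list was up after quantile normalization. Of 20 macrophage genes, Adgre1 was higher, Tyrobp, whose knockdown mean of 2.52 was at background, was lower, and 2 were called over the list alone (adjusted p = 0.381). Of 19 endothelial genes, Ramp2, Tek and Eng were higher, 0 were lower and 3 were called over the list alone (adjusted p = 0.511). Eng was not called after quantile normalization (adjusted p = 0.124) or with the mean of its probe sets (adjusted p = 0.122). The unfolded protein response list of 26 genes had Edem1 and Creld2 higher, Manf lower and 0 called over the list alone (adjusted p = 0.323), with 0 higher and 3 lower after quantile normalization but 5 higher and 1 lower after median centring. The hypoxia and glycolysis list of 23 genes had Pfkp and Pdk1 higher, Vegfa lower and 5 called over the list alone (adjusted p = 0.232), with 4 higher after median centring and 2 called without knockdown replicate 1. A dimmer probe set of Vegfa, above background, had a log2 fold change of 0.009, against -0.705 for the brightest. Of 26 peroxisome genes, Phyh, Pex6, Pex19, Ech1 and Pecr were lower, Abcd2 and Amacr were higher, and 7 were called over the list alone (adjusted p = 0.924). Without knockdown replicates 1 and 2, the endothelial list had 0 and 1 higher members (and 2 lower ones without scramble replicate 2), and the unfolded protein response list had 0 called each time. The peroxisome list had 1 higher and 1 lower member each time, the macrophage list 1 and 0 called members (and 1 higher and 3 lower ones without scramble replicate 2), and the skeletal muscle list 3 and 1.

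**Figure D3:**
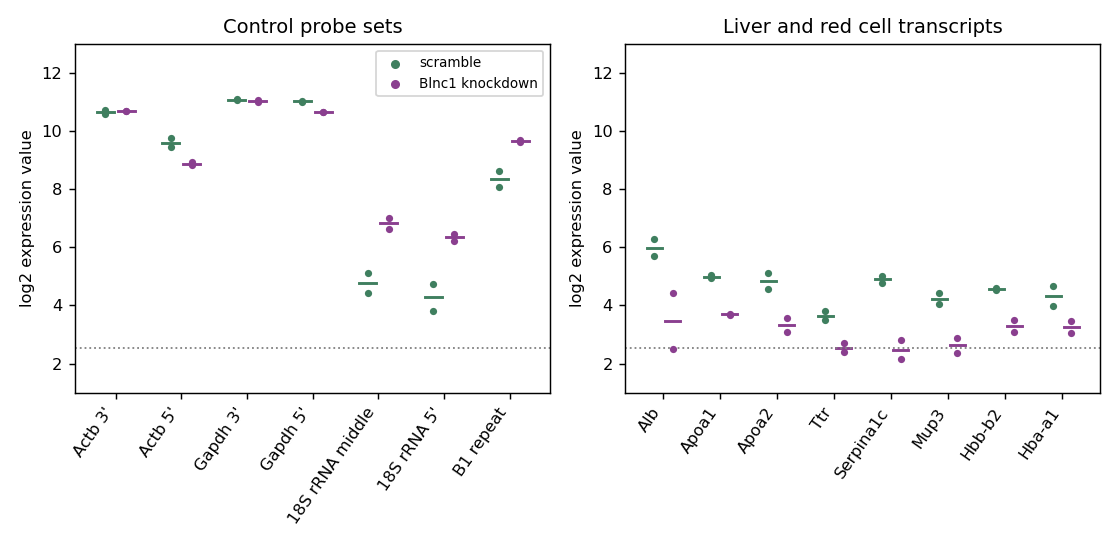
Log2 expression values per array (points) and group means (bars) for control probe sets (left) and for liver and red cell transcripts (right), in scramble (green) and Blnc1 knockdown (purple), with the background log2 value of 2.55 as a dotted line. The 3' probe sets of Actb read 10.67 and 10.70 in the groups and the 5' probe sets 9.60 and 8.88, and Alb read 6.28 and 5.70 in scramble against 4.43 and 2.50 in knockdown.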

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

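The tests of matrix genes against RNA integrity, of adipocyte against thermogenic genes and of liver transcripts were chosen only after the results were seen. The control probe sets and the probe sets without a gene name stand outside the comparison of genes and carried a signal of their own. The middle and 5' probe sets of 18S ribosomal RNA were higher in knockdown by 2.05 and 2.07 log2 units (limma, adjusted p = 0.00076 and 0.000821 over the control probe sets), while the 3' one had a log2 fold change of 0.40 (adjusted p = 0.284). The B1 repeat probe set was higher by 1.31, a B2 repeat probe set by 0.64 and the 3' probe set of the Pcx control by 0.35 (adjusted p = 0.000821, 0.00641 and 0.0278). A brighter B2 repeat probe set had a log2 fold change of 0.26 (limma, adjusted p = 0.0521 over the control probe sets). Of 15588 probe sets without a gene name in the annotation used here, 1472 (9.44%) passed an adjusted p of 0.05 over them alone, 841 higher and 631 lower, and 265 of these moved by at least 1 log2 unit.

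Extracellular matrix genes were higher on the arrays that also had the larger 3'/5' ratios. Broken RNA can lower a 5' signal and adds no transcript. Where arrays are scaled to each other, though, other readings could rise as 5' signals fall, and the exact scaling is not known here. The list median of 0.73 (95% bootstrap interval 0.59 to 0.88) lay above the changes of the 3' control probe sets of Actb and Gapdh, 0.03 and -0.05. The 3' probe sets of Pcx and 18S ribosomal RNA moved by 0.35 and 0.40, the latter with a standard error of 0.285. Other controls rose above the interval: the middle and 5' probe sets of 18S ribosomal RNA by 2.05 and 2.07, and the B1 repeat by 1.31. Some signals thus did rise on the arrays with larger 3'/5' ratios. The list rose more than the 3' probe sets of Actb and Gapdh, but this does not decide whether RNA quality contributed. A change in the cells after Blnc1 knockdown, an effect of the shRNA on other targets and a difference in culture between the groups were not tested and stay open, and may each contribute.

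Thermogenic genes were lower in knockdown, where 5' signals were also weaker, with the Actb 5' probe set down by a log2 fold change of -0.72 (adjusted p = 0.00332 over the control probe sets). If position along the transcript were the source, other probe sets of the called lower genes could go either way. They could also be lower, where they lie far from the 3' end. Of 7 other probe sets above background, 6 were lower and 1, of Pank1, was higher (exact sign test, two-sided, p = 0.125). Ppara gave 2 of the 7. The positions of the probe sets were not known here, so this count cannot decide the question. A lower share of differentiated fat cells may lower all fat cell genes alike. The general adipocyte median exceeded the thermogenic one by 0.25 (95% bootstrap interval -0.001 to 0.634), or by 0.20 (-0.07 to 0.63) without genes near the top of the scale, so neither that nor a change of the thermogenic genes themselves can be excluded.

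Liver transcripts were higher on the scramble arrays. Of 35 hepatocyte genes, 16 were lower in knockdown and 2, Kng1 and Trf, were higher, with 22 called over the list alone, a camera adjusted p of 0.000129 and adjusted p = 0.313 with an estimated correlation. RNA from liver in the scramble samples may account for this. The median scramble minus knockdown difference was 0.45 (95% bootstrap interval 0.17 to 0.82). Apoa1, Apoa2 and Ttr, among the most abundant liver messages, read 4.95, 5.11 and 3.79 on scramble replicate 1. On a scramble array 80% of the members were above background. That share says little by itself, because only 4210 of all 17097 tested genes had both groups at background. The red cell genes Hbb-b2 and Hba-a1, picked after their values were seen, had log2 fold changes of -1.28 and -1.08 (adjusted p = 0.0026 and 0.0235). The liver signal moved with the groups, so liver RNA and a change of these genes in the fat cells cannot be told apart here, and 20 of the 35 genes were above background in the knockdown mean as well, against 28 in scramble.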

How the results depend on the processing

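The median centring of the gene lists, the list counts under other scalings and the comparison without bright genes were chosen after the data had been seen. The number of genes changed by at least 1 log2 unit, 430, ranged from 315 to 490 where genes were tested. Testing every probe set counted 6356 probe sets (3933 higher, 2423 lower, 1025 by at least 1 log2 unit), because more features are tested. Asking for a change beyond 0.5 left 337 genes (290 higher, 47 lower), because that test is stricter. Leaving out 1 array gave 1050 to 2841 called genes, 795 to 1681 higher and 255 to 1168 lower. Calls fell most without knockdown replicate 1 or 2, where the scramble pair alone gave the residual error. The median SD of the pairs was 0.0935 in scramble and 0.0744 in knockdown. In those fits the oxidative phosphorylation median was -0.194 and -0.185 (-0.189 with all arrays), and the thermogenic one -0.332 and -0.339 (-0.313). The inflammatory median moved more, to 0.203 and 0.434 (0.333). These fits rest on fewer arrays. Quantile normalization called 3078 genes, 2547 of them shared, median centring 3227 (2785 shared), and eBayes with a trend 4370 (3085 shared).

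All 13 list calls were lost with an estimated correlation, which left 0. The camera adjusted p was then 0.197 for the thermogenic and for the oxidative phosphorylation list. With an estimate, camera uses the 2 residual degrees of freedom, and with the preset far more. Few lists could pass that way, so the loss does not by itself show correlated genes. At an unadjusted p under 0.05, 2 lists passed with the estimate, extracellular matrix (0.0127) and oxidative phosphorylation (0.0328). The estimated correlations of these 2 lists, 0.0077 and 0.0043, were below the preset 0.01. Their unadjusted camera p-values with the preset were 1.66e-17 and 2.36e-06. The loss of these 2 calls therefore did not come from a correlation above the preset. Estimates were also below the preset for smooth muscle and myofibroblast (0.0087), mitochondrial biogenesis (-0.0201), preadipocyte (-0.0181), inflammatory (-0.031) and brown fat transcription regulator (-0.015) genes. These lists lost their calls too. Other called lists, such as lipogenesis (0.361), had a higher estimate. With fry 16 passed, adding fatty acid oxidation (0.0291), TCA cycle (0.0402) and skeletal muscle (0.022). The tests ask different things: fry whether the genes of a list change together, camera whether they change more than other genes. With 18.5% of all genes called, the former is easier to pass. In camera, the mean of all probe sets added white fat selective genes (0.0218). The 13 calls held under quantile normalization, median centring and each left-out array and the replicate block, and p53 targets were lost without dim probe sets (0.0921). The general adipocyte list turned up with fry (0.688) and without scramble replicate 1 or knockdown replicate 2; its adjusted p over the left-out arrays was 0.792 to 0.894. The skeletal muscle list turned up after quantile normalization (adjusted p = 0.771). Fabp4 changed sign after quantile normalization (-0.037), with the mean of its probe sets (-0.18) and over the left-out arrays (-0.033 to 0.075), and Zbtb7b over the left-out arrays (-0.341 to 0.056); neither was called, and the cause was not tested.

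Replicate numbers did not pair the samples: same-numbered arrays had deviations correlated at 0.036 over all probe sets and 0.014 above background, with 2 pairs. With the replicate block 3179 genes were called, 2948 of them shared, and Edem1 (0.0511) and Creld2 (0.0553) were no longer called. Of 113 named genes, 29 and 33 lost their call without knockdown replicates 1 and 2, and 11 and 4 without scramble replicates 1 and 2. Quantile normalization ended 3 of their calls and the mean of all probe sets 4, and eBayes with a trend added 2, Ebf2 and Pparg. Signal over background limits Dio2, Serpina1c, Cd34, Tyrobp, Pmaip1 and Psg28, whose lower group was at background.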

Other observations

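The tests of FOXO and PPAR targets used lists drawn up after Depp1, Pdk4, Angptl4 and Ppara had been seen among the lower genes, which are left out of them. The histone genes and the genes of the next paragraph were picked after their values were seen.

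Of 15 measured histone genes, 11 were higher and 0 lower in knockdown, with a median log2 fold change of 1.10; near-identical copies are not independent, and no enrichment was tested. H2bc4, one of the bright ones, read 9.80 and 9.60 in scramble and 10.78 and 10.79 in knockdown (limma adjusted p = 0.00161). Most histone messages lack a poly(A) tail, as does 18S ribosomal RNA. The middle and 5' probe sets of 18S were higher by 2.05 and 2.07 on the same arrays, and the 3' one by 0.40 (limma adjusted p = 0.284 over the control probe sets). The B1 repeat probe set was higher by 1.31. On the cell cycle list 18 of 39 genes were higher and 0 lower. What raised the histone genes was not tested. The genes of the lipid-regulating factors Angptl8 and Angptl4 moved apart, with log2 fold changes of 2.10 and -1.93 (adjusted p = 0.000247 and 0.000338). Arrdc4, which is induced by glucose, was higher by 2.18 (adjusted p = 0.000342) and Gpat3, an enzyme of triglyceride synthesis, by 2.14 (adjusted p = 0.000328). The germline genes Ott and Astx6 were 3.82-fold and 3.39-fold lower in knockdown (adjusted p = 0.00097 and 0.000344). The pregnancy-specific glycoprotein gene Psg28 read 4.45 and 4.28 in scramble and 2.46 and 2.47, at background, in knockdown (adjusted p = 0.000328).

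Called genes were checked against their other probe sets above background, a check added after the data had been seen. Of 1286 other probe sets of called higher genes, 990 (77.0%) had the same sign, as did 432 of 558 (77.4%) for called lower genes.

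Depp1, Pdk4 and Angptl4 are FOXO targets, and lower FOXO activity might lower them together. The other FOXO targets on the list had a median log2 fold change of 0.021 (95% bootstrap interval -0.22 to 0.23, camera adjusted p = 0.924 over the lists added later). Of 18 measured, 3 were lower (Bcl6, Cited2 and Sod2) and 2 higher (Gadd45a and Sesn3), with 5 called over the list alone, and with members going both ways the list does not settle the question. Ppara, Pdk4 and Angptl4 might also fall together through lower activity of PPAR alpha and delta. Of 24 measured targets of these receptors, 7 were lower and 3 higher (Cpt1a, Acot1 and Acot2), with 12 called over the list alone, a median of -0.009 (95% bootstrap interval -0.35 to 0.16) and a camera adjusted p of 0.789, which leaves this open as well.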
